A study of Homo sapiens with 16 samples.

How the data were processed

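The study measured accessible chromatin by ATAC-seq on 55000 viable cells per library, per the labels' protocols, in 16 libraries of 8 groups: CAL27, SCC13, undifferentiated keratinocytes and differentiated keratinocytes, each with control or p63 siRNA and 2 libraries. Groups were taken from the sample titles. The deposited files hold raw counts, 1 whole number for each library over 177375 regions that are the same in every file. The genome build is hg19, per the submitters' processing notes; the aligner, the read filters, the peak caller, the way the common regions were made and the way reads or insertions were counted are not given in the sources used here. Whether reads placed at more than 1 position were kept, and whether both mates of a pair were counted, is therefore unknown. The first could change counts in repeated sequence and the second counts and their spread at every region. In replicate 1 of the undifferentiated controls 25.7% of the counts from 1 to 20 were odd, against 44.2% to 50.0% in the other 15 libraries. Counting of both mates in that library alone could give this and was not tested. It would bear on every comparison with the undifferentiated controls, where scaling takes up a common factor but not the added noise. Without that library 52664 regions were called for p63 siRNA in undifferentiated keratinocytes, and 52769 without the other control.

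Region starts were read as counted from 0, an assumption because the files have no header, and are printed counted from 1. The 273 regions on chromosome Y were left out before any step, because the keratinocytes come from people, which left 177102 regions with a median width of 472 bp. One named region on chromosome X is not described, and X was kept out of chromosome and window summaries and of the lists chosen after the values were seen. No gene annotation of the hg19 build was used here, so no region was tied to a gene and the planned gene lists, motif searches and corrections for GC content were not run.

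The 10 comparisons were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on the deposited counts. TMM factors were used, and a filter by group with a minimum of 10 counts left 176693 regions. A robust quasi-likelihood model of all 16 libraries had 1 coefficient for each group (8 residual degrees of freedom, common dispersion 0.0442). Regions were called at a Benjamini-Hochberg adjusted p under 0.05. With 2 libraries in a group, the spread is shared over all groups. CPM values use TMM factors. The floor for a count of 0 was 3 counts per library, which covers counting error only, since reads without molecular identifiers are not independent molecules. The rule for named regions and the tests of the 10 comparisons were fixed before the data were examined. The part of the rule on genes, among them those of p63 and FOXK1, was not used, since regions were not tied to genes. For regions the rule took for the 4 knockdowns and for differentiation with control siRNA the 5 higher and 5 lower called regions with the largest absolute log2 change among those with a mean of at least 2 on the log2 CPM scale, both libraries of one group above both of the other, and at least 100 kb apart. It took 2 and 2 for the other comparisons. Because many of these sat near 0, the lists were also drawn with at least 1 CPM in the higher group and in at least 1 carcinoma group, chosen after the values were seen.

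The test was tried on simulated data for the CAL27 comparison, with counts drawn from the real means and 200 of 176573 regions changed: 94% of 4-fold gains and 80% of losses to 0.25 were recovered, 4% of gains of 2-fold and 4% of losses to 0.5, with 3 false calls. Small changes are thus often missed where few regions change. The window test, in which called regions were placed at random 1000 times among autosomal regions of like mean level (20 levels), was tried with 200 placements: it gave a permutation p of 0.13 for simulated random calls, and 0.005, the smallest 200 placements can give, for a planted window of 60 calls, which it found.

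The alternatives were DESeq2 1.42.0 with its own size factors, DESeq2 size factors or total counts in edgeR, loess offsets (span 0.3) on mean log count or on region width, no count filter or a minimum of 50, only the libraries compared, a replicate block, each library left out in turn, a log2 change of at least 1, and for overlaps an adjusted p of 0.01. Added after seeing the data were a fit without regions holding 8 counts or fewer over the 8 carcinoma libraries, and an offset of the median per library in each 5 Mb window. Figures were drawn with matplotlib 3.10.9.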

Results

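Chromatin accessibility was measured by ATAC-seq, an assay in which a transposase inserts sequencing adapters into open DNA, in 16 libraries. CAL27 and SCC13, both established human squamous cell carcinoma lines, were set beside primary human keratinocytes kept undifferentiated (day 0) or differentiated for 3 days in 1.2 mM calcium. In each of these 4 contexts, cells had received a control siRNA or an siRNA against p63, a transcription factor of stratified epithelia. Each of the 8 groups held 2 libraries, which the labels call biological replicates. Counts over one common set of 177102 regions totalled from 33415007 to 74798652 per library. The differentiated controls were deepest, at 71041068 and 74798652, and replicate 2 of the undifferentiated cells with p63 siRNA was shallowest, at 33415007. Libraries of one group correlated across regions at r of 0.962 to 0.987 on log2 CPM, and in every group they differed by more than sampling noise (chi-square per degree of freedom 3.88 to 11.34). The knockdown acts on RNA, so accessibility does not show whether p63 itself was lowered. Regions are given by hg19 coordinates and levels as counts scaled to library size (CPM, mean ± SD, n = 2 libraries).

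**Figure D1:**
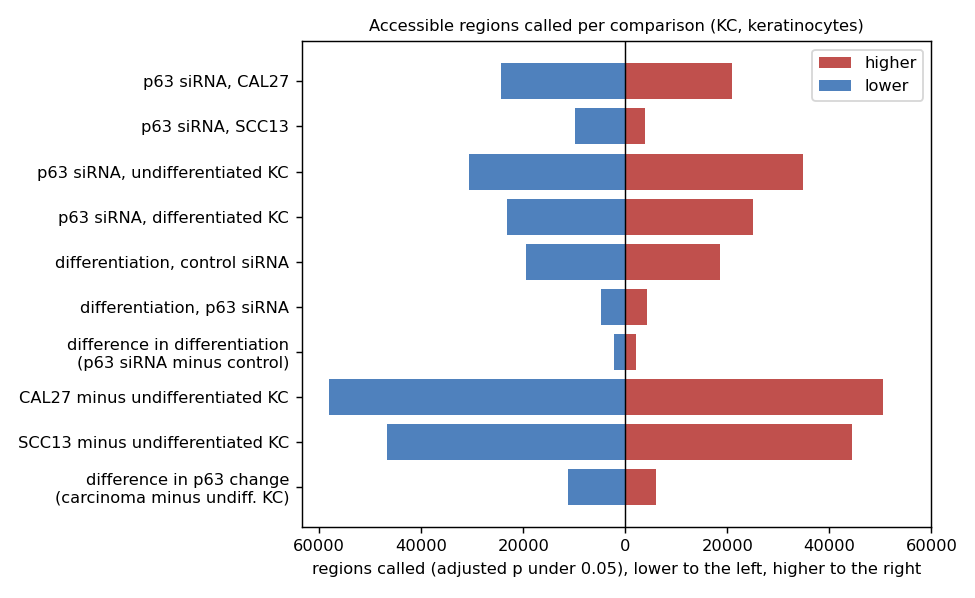
Regions called lower (blue, to the left of 0) and higher (red, to the right) in each of the 10 comparisons, as numbers of regions. For a difference between changes, lower and higher mean a more negative and a more positive difference. Calls with p63 siRNA ranged from 3912 higher and 9771 lower in SCC13 to 34735 higher and 30718 lower in undifferentiated keratinocytes.

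The first question was which regions depend on p63 in CAL27. With p63 siRNA, 24383 of 176693 tested regions (13.8%) fell and 20819 (11.8%) rose, with median log2 changes of -1.66 and 1.45 (median SE 0.37). On chromosome 8, the region from 119239560 to 119240166 fell from 12.9 ± 2.7 to 0.532 ± 0.054 CPM, a 24.1-fold loss (log2 change -4.59 ± 0.46 SE, edgeR adjusted p = 2.2e-06). Another, at chromosome 2, 67675839 to 67676313, fell from 10.4 ± 0.56 to 0.454 ± 0.42 CPM. Among gains, the region at chromosome 12, 1780023 to 1780483, rose from 0.543 ± 0.19 to 9.34 ± 0.0031 CPM, 17.1-fold (log2 change 4.10 ± 0.38 SE, edgeR adjusted p = 1.2e-06). These 3 regions reach 1 CPM in a carcinoma group and were chosen after the values were seen. The reason was that 4 of the 5 higher and 2 of the 5 lower regions named by the rule fixed in advance stayed under 1 CPM in both groups. Of the named regions above that level, chromosome 8, 37282371 to 37282699, rose from 0.109 ± 0.15 to 2.73 ± 1.4 CPM, and chromosome 1, 23988331 to 23988905, fell from 4.53 ± 1.3 to 0.0909 ± 0.019 CPM. The median control level was 3.23 CPM for regions that fell, 1.62 CPM for regions not called and 1.35 CPM for those that rose. Control libraries enter both this level and the fold change, so part of the difference follows from selection. Gains were 46.1% of the called regions, but 51.5% and 51.3% with offsets on mean level and on region width, so which direction was the more frequent is not settled. Without replicate 1 of the CAL27 controls the number of called regions was 28493 in place of 45202.

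In SCC13, p63 siRNA lowered 9771 regions (5.5%) and raised 3912 (2.2%), so that 28.6% of the called regions were gains. Accessibility at chromosome 1, 33470227 to 33470734, fell from 8.36 ± 2.4 to 0.374 ± 0.15 CPM (log2 change -4.46 ± 0.36 SE, edgeR adjusted p = 3.5e-06). That at chromosome 14, 90267330 to 90267970, fell from 15.8 ± 5.7 to 0.577 ± 0.14 CPM. A region on chromosome 14, 61798584 to 61799180, rose from 1.53 ± 0.29 to 7.58 ± 1.2 CPM (log2 change 2.29 ± 0.24 SE, edgeR adjusted p = 2e-05) while CAL27 held 0.253 ± 0.018 and 0.208 ± 0.036 CPM there. All 3 were named by the rule. The number of called regions, 13683, was 30134 from the SCC13 libraries alone, where the CAL27 libraries alone gave 40181 rather than 45202. Whether the 2 lines differ in their response was not tested. The SCC13 number was 2724, 6292 and 3572 without replicate 1 of the controls, replicate 1 with p63 siRNA and replicate 2 with p63 siRNA. The share of gains was 7.7% (211 regions) and 12.2% (436) without replicate 1 of the controls and replicate 2 with p63 siRNA, 39.4% with an offset on region width and 40.3% (12137) from the SCC13 libraries alone. Losses were the more frequent in each of these settings, but the number of gains is poorly fixed.

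In undifferentiated keratinocytes p63 siRNA raised 34735 regions (19.7%) and lowered 30718 (17.4%). The total, 65453, was the largest of the 4 contexts in this fit, but from the libraries compared alone it was 54158 beside 54044 in differentiated keratinocytes, and a difference in number was not tested. On chromosome 16, the region from 31286314 to 31287021 fell from 24.9 ± 5.9 to 1.19 ± 0.39 CPM (log2 change -4.41 ± 0.33 SE, edgeR adjusted p = 1.9e-07). A further loss, at chromosome 11, 86174158 to 86174608, fell from 17.9 ± 1.7 to 0.884 ± 0.26 CPM. Among gains, the region at chromosome 13, 39597867 to 39598383, rose from 0.581 ± 0.29 to 11.5 ± 0.76 CPM (log2 change 4.30 ± 0.32 SE, edgeR adjusted p = 2.1e-07). Accessibility at chromosome 5, 71953816 to 71954429, rose from 0.26 ± 0.17 to 6.34 ± 0.091 CPM. Lost regions had a median control level of 5.86 CPM and gained ones 0.781 CPM, with the limit named for CAL27. Gains were 53.1% of the called regions and 64.7% with total counts in place of TMM factors. They were 46.8% to 49.6% with DESeq2, its size factors, either loess offset, the libraries compared alone or, added after seeing the data, the 5 Mb offset, so which direction was the more frequent is not settled. The largest named loss, at chromosome 9, 46715094 to 46716176 (16.3 ± 4.7 to 0.108 ± 0.058 CPM), lies in a region with almost no counts in the carcinoma libraries, a class described with the differentiated cells.

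In differentiated keratinocytes p63 siRNA raised 25055 regions (14.2%) and lowered 23288 (13.2%). On chromosome 17, the region from 31560862 to 31561163 rose from 0.975 ± 0.044 to 14.7 ± 2.4 CPM (log2 change 3.91 ± 0.29 SE, edgeR adjusted p = 1.3e-07). A gain at chromosome 8, 86951507 to 86952330, went from 0.891 ± 0.4 to 13.9 ± 0.69 CPM. All 5 lower regions named by the rule had 0 counts in both p63 siRNA libraries, led by chromosome 15, 83182617 to 83183313, at 36.3 ± 5.6 CPM in the controls. This is at least 640-fold lower against a floor of 3 counts per library. Those 5 regions also held at most 3 counts over the 8 carcinoma libraries together. In undifferentiated cells p63 siRNA took the first from 45.4 ± 7.8 to 8.47 ± 0.39 CPM and chromosome 15, 82798034 to 82798742, from 44.7 ± 10 to 8.36 ± 0.64 CPM. Means at the others were not lower. They went from 6.93 ± 3.5 to 12.9 ± 3.7 CPM at chromosome 12, 64704 to 65126, and from 7.63 ± 4.4 to 12.5 ± 4.8 CPM at chromosome 2, 114332162 to 114332467. At chromosome 15, 102492222 to 102492592, they went from 6.39 ± 1.8 to 10.8 ± 1.9 CPM. There were 633 regions with 8 counts or fewer in the carcinoma libraries and at least 1 CPM in the undifferentiated controls. Of these, 320 (50.6%) were under 0.1 of control in the differentiated cells with p63 siRNA, against 0.2% of the 91792 regions with over 400 carcinoma counts. In undifferentiated cells with p63 siRNA 136 (21.5%) of the 633 were so low, against 0.2% of the 91792. On chromosome 9 lay 181 of the 633 and 4054 of the 91792. Losses at regions that reach 1 CPM in a carcinoma group were then listed, a rule chosen after seeing this. The largest, at chromosome 9, 41954075 to 41955243, fell from 19.5 ± 3.6 to 0.732 ± 0.44 CPM. It held at most 1.05 ± 0.24 CPM in a carcinoma group, and 20.5 ± 2.9 and 21 ± 0.93 CPM in undifferentiated cells with control and p63 siRNA. The 1 CPM rule thus does not remove every region with few carcinoma counts. Others were chromosome 5, 136567197 to 136567743, which fell from 10.3 ± 1.5 to 0.424 ± 0.085 CPM, and chromosome 2, 67675839 to 67676313, which fell from 11.8 ± 0.23 to 0.654 ± 0.21 CPM. Left without replicate 1 of the controls or replicate 2 with p63 siRNA, the fit called 29800 or 30746 regions in place of 48343. Gains were 51.8% of the calls, but 48.5% from the libraries compared alone and 48.1% and 48.8% without replicates 1 and 2 of the controls, so the more frequent direction is not settled here either.

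**Figure D2:**
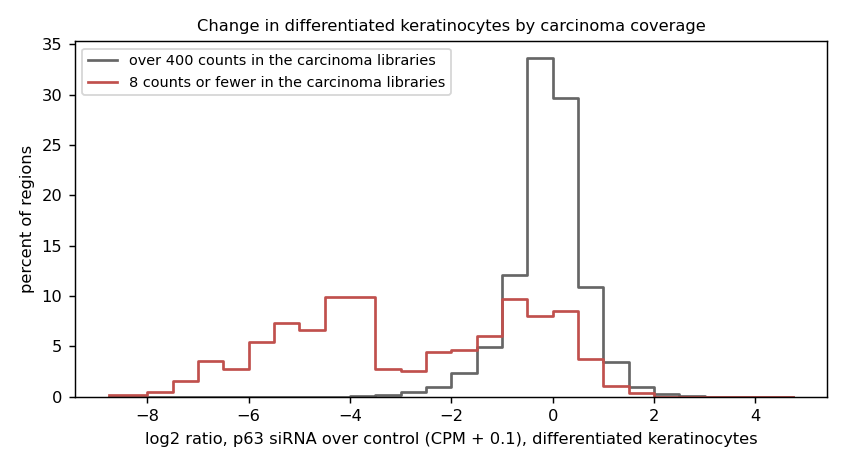
Percent of regions (vertical axis) against the log2 ratio of p63 siRNA to control in differentiated keratinocytes (horizontal axis, mean CPM plus 0.1 in each group), for 584 regions with 8 carcinoma counts or fewer (red) and 86669 regions with over 400 (grey), all with at least 1 CPM in the undifferentiated and the differentiated controls. The red curve has a group far below 0 that the grey curve lacks.

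The 4 knockdowns, which share no library, were then compared region by region. Of the 9771 regions lower in SCC13, 6991 were also lower in CAL27, against 1348 for independent lists of these sizes, and 2268 regions rose in both lines against 461. The undifferentiated and differentiated keratinocytes shared 16037 losses against 4049 and 16639 gains against 4925. In all 4 contexts 4426 regions fell, where independent lists would give 30.9, and 1160 rose, where they would give 12.8. Independent lists take every region as equally likely to be called. Lost regions had higher control levels than regions not called in all 4 contexts, and levels correlated between contexts, so part of each excess may come from level. The SCC13 calls, far fewer without some single libraries, also bound the numbers shared with SCC13. At chromosome 8, 119239560 to 119240166, accessibility fell in every context, with log2 changes of -4.59 in CAL27, -4.44 in SCC13, -3.89 in undifferentiated and -3.97 in differentiated keratinocytes. That at chromosome 17, 31560862 to 31561163, rose in every context, by 2.77, 2.02, 3.19 and 3.91 on the same scale. Both were named after the values were seen, as having the largest smallest change over the 4 contexts. Across regions, which are not independent replicates, the fold changes correlated at r of 0.50 between the lines, 0.70 between the keratinocyte states and 0.38 to 0.50 between a line and a keratinocyte state. At an adjusted p of 0.01 the numbers common to all 4 contexts were 2015 lower and 259 higher, and 758 regions rose in all 4 with a log2 change of at least 1.

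**Figure D3:**
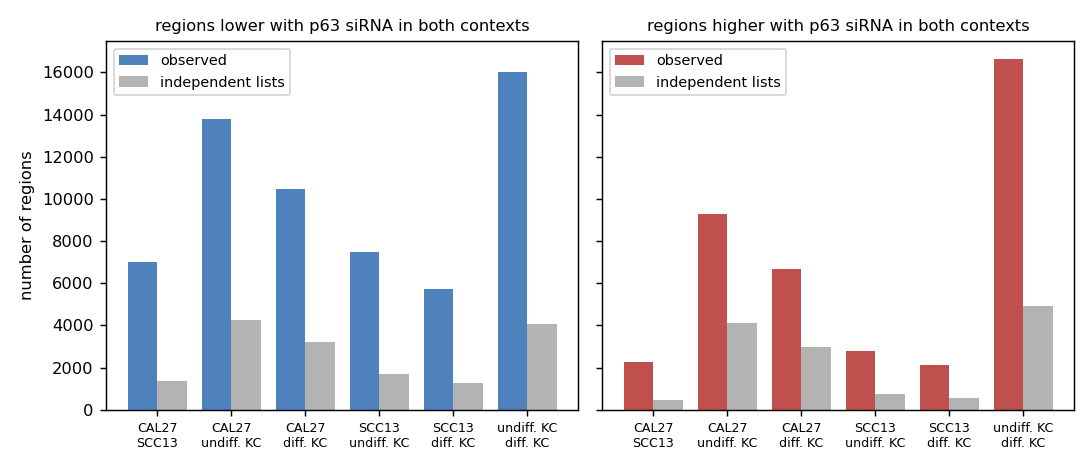
Number of regions lower (left panel) or higher (right panel) with p63 siRNA in both contexts of each of the 6 pairs, coloured bars, beside the number for independent lists of the same sizes, grey bars. Every coloured bar is above its grey bar, for example 6991 against 1348 for losses in both lines and 16639 against 4925 for gains in both keratinocyte states. The lowest ratio, 2.26, was for gains in CAL27 and differentiated keratinocytes, 6664 against 2952. The grey bars are not matched on the level of the regions.

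The title of the study concerns a cancer-specific part of p63 action, so the change in the carcinoma lines was tested against that in undifferentiated keratinocytes. The mean log2 change of both lines was more negative at 11234 regions and more positive at 5992. Most of these were regions that moved in the keratinocytes: 9200 of the 11234 rose there, and 4708 of the 5992 fell there. This relation partly follows from the keratinocyte libraries entering both tests. At 7453 of the 11234 and 3930 of the 5992, neither line was called. Of the 6991 regions lower in both lines, 5913 (84.6%) were also lower in undifferentiated keratinocytes, and 381 were not lower there and differed by the test of the difference. At these 381 regions the median log2 change was -1.84 in CAL27, -1.50 in SCC13 and -0.03 in undifferentiated keratinocytes, with median control levels of 3.73, 3.48 and 3.24 CPM. The contrast of these changes follows from how the regions were selected and is no test. One of them, at chromosome 2, 210256516 to 210257305, was chosen after its values were seen. It fell from 12.6 ± 1.8 to 2.22 ± 0.28 CPM in CAL27 and from 6.34 ± 1.9 to 2.95 ± 0.79 CPM in SCC13, and rose from 2.54 ± 0.7 to 5.33 ± 0.67 CPM in undifferentiated keratinocytes. In the mirrored direction 167 regions rose in both lines, were not called higher in undifferentiated keratinocytes and differed by the test of the difference. Of the 381 and the 167, 67 and 24 were called in the same direction in differentiated keratinocytes. More positive differences, which need not be gains in the lines, made up 34.8% of the 17226 called. That share was 14.5% with total counts only, 44.9% with DESeq2 and 51.5% with an offset on region width. The number called was 10341 without replicate 2 of the SCC13 controls and 7896 without replicate 2 of the undifferentiated cells with p63 siRNA.

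Calcium-induced differentiation with control siRNA raised 18481 regions (10.5%) and lowered 19373 (11%), with median log2 changes of 1.60 and -1.28. Chromatin at chromosome 3, 134097586 to 134097969, closed from 16.7 ± 3.3 CPM at day 0 to 0.713 ± 0.089 CPM at day 3 (log2 change -4.55 ± 0.37 SE, edgeR adjusted p = 4.4e-07). The region from 124271456 to 124272111 on chromosome 5 closed from 15.4 ± 1.1 to 0.617 ± 0.011 CPM. A region at chromosome 7, 48498497 to 48499222, opened from 0.921 ± 0.29 to 14.1 ± 1.6 CPM (log2 change 3.93 ± 0.54 SE, edgeR adjusted p = 0.00013). The region from 50717859 to 50718903 on chromosome 19 opened from 0.498 ± 0.37 to 10.6 ± 3.4 CPM. The number of called regions was 20539 and 24947 without replicate 1 and replicate 2 of the differentiated controls, in place of 37854. The regions that closed had a median level of 5.36 CPM at day 0, and those that opened 0.804 CPM, where the day 0 controls again enter both the level and the change. Gains were 48.8% of the calls, 56.7% with total counts only, and 51.1% and 51.2% without replicates 1 and 2 of the differentiated controls.

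With p63 siRNA the same differentiation step changed 4294 regions upward and 4848 downward. The labels put seeding 48 hours after transfection. If the days run from seeding, differentiated cells were also further in time from the siRNA. That time and differentiation cannot then be told apart here. Of the 18481 regions that opened with control siRNA, 2331 (12.6%) also opened with p63 siRNA, and their median log2 change as a whole list was 0.50 rather than 1.60. Of the 19373 that closed, 2713 (14%) closed again, with a median of -0.46 rather than -1.28. The sign was kept at 82.5% and 84% of them. Since the lists were chosen on the control change, some shrinkage arises from selection alone. The difference itself was called at 4163 regions, and it made the change smaller at 1698 of the opened and 1840 of the closed regions. At chromosome 3, 134097586 to 134097969, which was named by the rule for this difference, undifferentiated cells with p63 siRNA already stood at 0.877 ± 0.36 CPM and differentiated ones at 0.624 ± 0.039 CPM. With p63 siRNA, the region at chromosome 3, 30120224 to 30120705, rose with differentiation from 1.67 ± 0.22 to 11.7 ± 0.24 CPM, and the region at chromosome 22, 23519282 to 23519921, from 0.444 ± 0.038 to 2.82 ± 0.83 CPM. These regions also opened with control siRNA, from 1.78 ± 1.3 to 6.59 ± 1.6 CPM and from 0.213 ± 0.032 to 1.43 ± 0.2 CPM. Both lower regions named for this step and for the difference, at chromosome 12, 64704 to 65126, and chromosome 2, 114332162 to 114332467, were near 0 in the carcinoma libraries and had 0 counts in differentiated cells with p63 siRNA. Calls with p63 siRNA numbered 4945 and 2557 without replicates 1 and 2 of the undifferentiated cells, and 4231 and 2813 without replicates 1 and 2 of the differentiated cells. Gains were 47% of calls, 35% with total counts only, 57.1% with DESeq2 size factors, 64.9% from the libraries compared alone and 28.1% without replicate 1 of the undifferentiated cells with p63 siRNA, so their share is not settled. The difference was called at 7343 regions by DESeq2, at 1597 without replicate 2 of the undifferentiated cells with p63 siRNA, at 1394 and 2558 without replicates 1 and 2 of the differentiated controls, and at 1847 and 2314 without replicates 1 and 2 of the differentiated cells with p63 siRNA. Positive differences, which need not be gains, made up 48.1% of these calls in the main fit. Their share was 32% with total counts only, 58.1% with DESeq2 size factors and 58.6% with DESeq2 itself. It was 59.8% with an offset on region width or, added after seeing the data, on the median of 5 Mb windows.

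The p63 siRNA change in undifferentiated keratinocytes was set beside their differentiation. Both lowered 11303 regions, where independent lists would share 3368, and both raised 12189, where they would share 3633. Only 247 regions fell with p63 siRNA and rose with differentiation, and 412 did the opposite. Accessibility at chromosome 5, 71953816 to 71954429, stood at 0.26 ± 0.17 CPM in undifferentiated controls, 6.34 ± 0.091 CPM after p63 siRNA and 3.95 ± 1.5 CPM after differentiation. These comparisons share the undifferentiated controls, which raises their relation with no effect at all. The correlation across regions was 0.61, against 0.53 in simulated unchanged groups, while the covariance was 0.634 against 0.08. With 1 control library used for each side, the correlation was 0.43 in both arrangements. Part of the overlap may come from the shared controls, and independent lists do not match regions on level. For p63 siRNA in differentiated cells, which shares the differentiated controls, the correlation with differentiation was 0.11 against -0.46 simulated, with a covariance of 0.108 against -0.067.

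**Figure D4:**
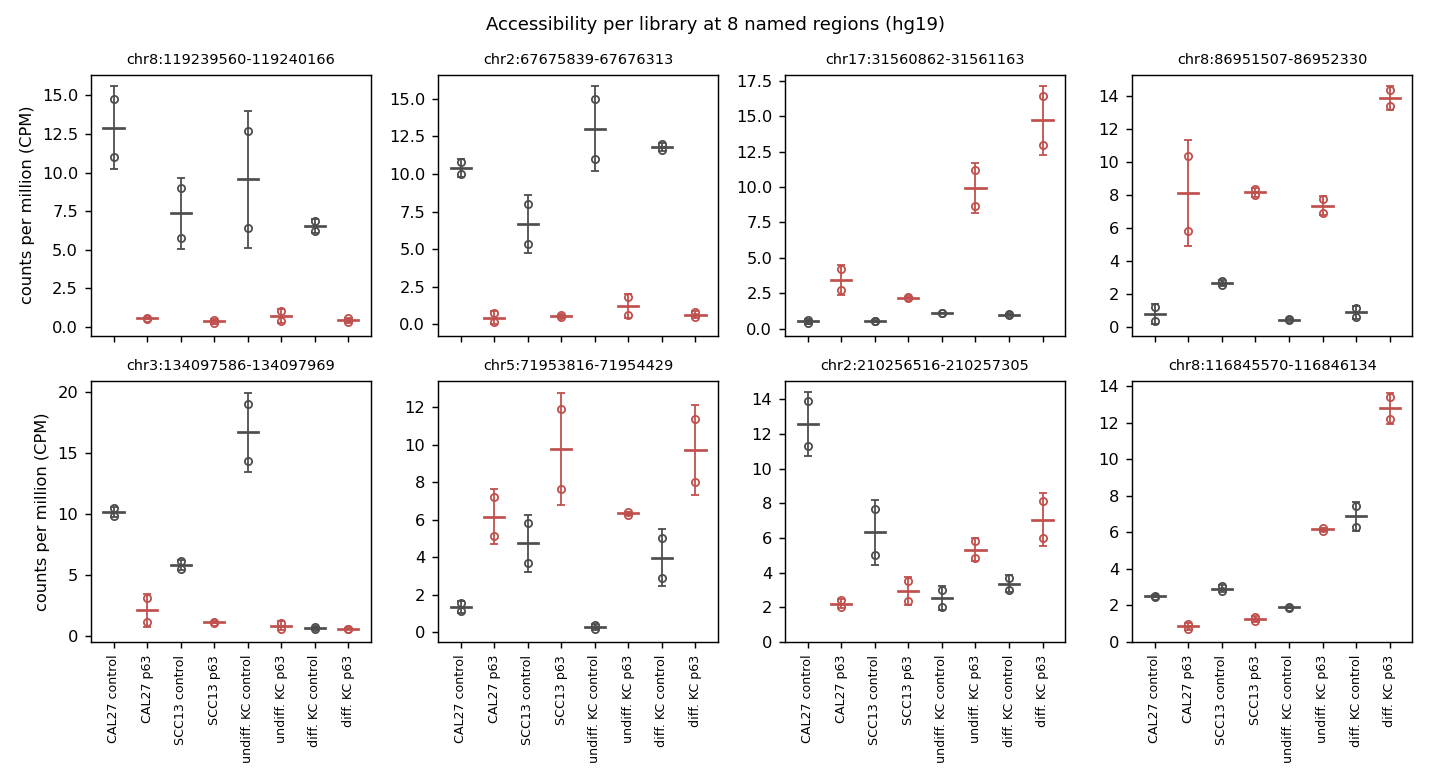
CPM per library (vertical axis) in the 8 groups (horizontal axis) at 8 regions, circles for libraries, horizontal lines for group means and error bars for the SD, control siRNA in grey and p63 siRNA in red. The top row holds 2 regions that fell and 2 that rose with p63 siRNA, such as chromosome 8, 119239560 to 119240166, and the bottom row holds a region closed and a region opened by differentiation and 2 regions that fell in both lines and rose in undifferentiated keratinocytes.

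At baseline, with control siRNA, CAL27 differed from undifferentiated keratinocytes at 108476 of 176693 regions (61.4%), 50470 higher and 58006 lower, and SCC13 at 91253 (51.6%), 44471 higher and 46782 lower. Among regions higher in a line, chromosome 14, 21175604 to 21176225, stood at 17.3 ± 1.5 CPM in CAL27 and 0.0473 ± 0.00038 CPM in keratinocytes, and chromosome 8, 143474951 to 143475568, at 42.7 ± 3.4 CPM in SCC13 and 0.142 ± 0.0011 CPM in keratinocytes. The keratinocyte levels rest on 4 and 12 counts over both libraries, so their small SDs do not show precision. The first lies under the floor of 0.071 CPM. The lower regions named by the rule had 0 counts in the line, such as chromosome 15, 84898572 to 84899297, at 46.0 ± 4.3 CPM in keratinocytes, and belong to the class that is near 0 in both lines. Whole chromosomes were shifted: the median log2 difference from keratinocytes was -1.07 on chromosome 4 and -0.85 on chromosome 18 in CAL27, and 0.59 on chromosome 8 and 0.44 on chromosome 14 in SCC13. The cell types were grown in different media, so the cell type and the medium cannot be told apart here. With total counts only, gains were 35.8% of the CAL27 calls rather than 46.5%.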

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

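The tests of closing by p63 siRNA, copy number, scaling and splits of the contexts were chosen only after the result was seen, and those of read placement, DNA loss and counts near 0 in the lines before. A second test of DNA loss, written when its value was already known, was dropped.

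The differentiation change differed with p63 siRNA at 4163 regions. The named regions were chromosome 6, 160097831 to 160099354 (difference in log2 change 4.19) and chromosome 3, 134097586 to 134097969 (4.02), where closing with differentiation was smaller with p63 siRNA (the first lost its call without replicate 1 of the differentiated cells with p63 siRNA, 3.25), and chromosome 12, 64704 to 65126 (-13.57) and chromosome 2, 114332162 to 114332467 (-13.34), where fitted values rest on a group at 0 counts and are no measure of size.

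Both of these last regions belong to a pattern: near-complete loss in differentiated keratinocytes with p63 siRNA at regions that hold almost no counts in the carcinoma libraries. Loss of the DNA in the carcinoma lines stays open as a cause of the low counts there: of 1231 regions with 4 counts or fewer in CAL27 and at least 1 CPM in undifferentiated controls, 45.5% were also so low in SCC13, under the 50% set for loss, but of the 738 so low in SCC13, 75.9% were in CAL27, and neither share bears on the differentiated cells. Handling of reads placed at more than 1 position that differed between libraries stays open: of 291 regions with at most 3 counts in each differentiated p63 siRNA library and at least 1 CPM in their controls, 82.5% were near 0 in the carcinoma libraries, against 0.53% of all tested regions, but this share restates the pattern and cannot separate its causes. Closing of these regions by p63 siRNA cannot be told apart from it, since 40.6% of the regions lost in differentiated cells were also lost in undifferentiated cells, near the 45.7% found among lost regions with over 400 carcinoma counts, and no mapping information was used. As a share of the whole class, 21.5% were lost in undifferentiated cells, against 0.2% of regions with over 400 carcinoma counts, so the pattern is not limited to differentiated cells. In the fit of the 175762 regions with over 8 carcinoma counts, which leaves out more than this class, 47655 regions were called for p63 siRNA in differentiated cells and 3728 for the difference. That fit keeps part of the pattern, since 14.1% of the 291 lost regions held over 8 and at most 80 carcinoma counts.

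The p63 siRNA change differed between the carcinoma lines and undifferentiated keratinocytes at 17226 regions. The named regions were chromosome 15, 83182617 to 83183313 (difference in log2 change 5.51) and chromosome 10, 48185407 to 48186559 (4.99), both with at most 11 counts over the carcinoma libraries, and chromosome 18, 6476835 to 6477482 (-4.66) and chromosome 11, 104658485 to 104659016 (-4.32), both of which rose in undifferentiated keratinocytes, from 1.3 ± 0.31 to 6.7 ± 0.075 CPM and from 0.545 ± 0.31 to 7.69 ± 2.5 CPM. At chromosome 18 CAL27 went from 0.0846 ± 0.086 CPM to 0 counts and SCC13 from 0.489 ± 0.031 to 0.681 ± 0.64 CPM, so that fitted value is no measure of size. The call at chromosome 15 was lost with total counts only (5.15), with the offset on mean level (5.15), in the fit of the libraries compared (5.32), and without any one control library or undifferentiated p63 siRNA library in the comparison or replicate 2 with p63 siRNA of CAL27 or SCC13 (3.72 to 5.68), and that at chromosome 18 without replicate 2 of the CAL27 controls (-3.78).

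For this carcinoma difference, 3.2% of the called regions lay under 0.2 CPM in all 4 carcinoma groups. This argues against counts that low in both lines at most of them. Regions near 0 in 1 line only, such as that at chromosome 18 in CAL27, were not counted, so low counts in a single line stay open. With total counts only 82.4% of the calls were called in the same direction, 61.6% with the offset on mean level and 76.4% with that on width. Scaling differences of that size are argued against as the whole cause. They moved the median change little beside the called differences (median log2 -2.04 and 1.15), so larger errors of scale were not tested. Setting each of 3 contexts in turn against the mean of the others gave 17226 regions for undifferentiated keratinocytes and at most 8333 for another context, so that only the real split, 1 of 3, was that large; 3 splits are too few for a share under 0.05. A difference between carcinoma and normal cells stays open, untested against growth medium and culture. Nor was it tested against the degree of p63 knockdown in each context, which accessibility does not show.

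The baseline differences of the lines are the third pattern. Copy number at the scale of 5 Mb windows is argued against as the whole cause, because 80.6% of the CAL27 calls were called in the same direction after the median of each 5 Mb window was removed. Gains or losses of DNA smaller than a window are not removed by this offset and were not tested. Scaling differences of the size tried are argued against as the whole cause, since 88.9% of the CAL27 calls were kept with total counts only and 85.7% and 86.3% with the offsets on mean level and width. Larger errors of scale were not tested. Whether copy number shapes broad shifts stays open. Window medians from control libraries and from p63 siRNA libraries correlated at 0.97 over 560 windows in CAL27 and 0.89 in SCC13, and 0.63 between the lines. Any stable difference between a line and keratinocytes would give the same agreement within a line. The value between the lines is raised by the undifferentiated controls that both share. These correlations therefore cannot decide it.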

How the results depend on the processing

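All alternatives were planned, except the fit without regions near 0 in the carcinoma libraries and the 5 Mb window offset, chosen after seeing the data. The numbers of called regions stayed within 1.5 times of the main value at 153 of the tested settings. The more frequent direction of calls changed under some settings for CAL27 (gains up to 51.5%), undifferentiated keratinocytes (down to 46.8%) and both differentiation steps (up to 56.7% and 64.9%). It changed for differentiated keratinocytes from the libraries compared alone (48.5%) and without either control library. It also changed for the differentiation difference (positive differences up to 59.8%) and the carcinoma difference (positive differences up to 51.5%). Opposite calls arose against keratinocytes with the 5 Mb offset (788 regions in CAL27, 113 in SCC13), in CAL27 with offsets on mean level (134) and width (15), and for p63 siRNA in differentiated cells with the 5 Mb offset (14). Exceptions in number follow. Calls in CAL27 ranged over left-out replicates from 28493 to 34103, in SCC13 from 2724 to 9338, in differentiated keratinocytes from 29800 to 34746, for differentiation with control siRNA from 20539 to 30043 and with p63 siRNA from 2557 to 4945, for the difference between these from 1394 to 3600, and for the carcinoma difference from 7896 to 19833. A count moved by over 1.5 times without replicate 1 of the controls in CAL27 (28493), without replicate 1 of the controls (2724) or replicate 1 (6292) or 2 (3572) with p63 siRNA in SCC13, without replicate 1 of the controls (29800) or replicate 2 with p63 siRNA (30746) in differentiated cells, and for differentiation without replicate 1 (20539) or 2 (24947) of the differentiated controls. It did so for differentiation with p63 siRNA without replicate 1 (4945) or 2 (2557) of the undifferentiated or 1 (4231) or 2 (2813) of the differentiated cells. For the differentiation difference it did so without replicate 2 of the undifferentiated cells with p63 siRNA (1597), replicate 1 (1394) or 2 (2558) of the differentiated controls, or replicate 1 (1847) or 2 (2314) with p63 siRNA, and for the carcinoma difference without replicate 2 of the SCC13 controls (10341) or of the undifferentiated cells with p63 siRNA (7896). With 1 library left in a group, that library is assumed to vary like the other groups. From the SCC13 libraries alone 30134 regions were called, by DESeq2 7343 for the differentiation difference. Regions common to all 4 contexts numbered 2015 lower and 259 higher at an adjusted p of 0.01, and 758 higher with a log2 change of at least 1; at that adjusted p all 12 overlaps of 2 contexts shrank by over 1.5 times, to between 476 and 9766 regions. The cause was not tested, except that left-out replicates and the stricter threshold make a smaller test. Total counts moved the median log2 change of all regions by 0.18 for undifferentiated keratinocytes, -0.29 and -0.11 for CAL27 and SCC13 against keratinocytes, -0.24 for the carcinoma difference and -0.16 for the differentiation difference; the width offset moved it by 0.11 for CAL27 and 0.13 for the carcinoma difference, and the offset on mean level by 0.11 for the latter. Among single regions and pairwise overlaps 1070 values kept direction and call and 52 lost the call or shrank by over 1.5 times.

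Replicate numbers gave 2 pairs in each context and nothing in the labels says they pair the libraries; deviations of same-numbered libraries correlated at 0.18 to 0.28 within contexts. With a replicate block 28029 regions were called in SCC13, 13892 for the differentiation difference and 37838 for the carcinoma difference; other counts stayed within 1.5 times. Fits of GC content, alone or with the block, gene lists and motifs were not run, as no genome of the build was used. Depth limits the calls at regions near the floor of 3 counts per library.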

Other observations

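The test on differentiation below was written before its result was seen, and the test on windows after.

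Regions changed by p63 siRNA in the carcinoma lines were set beside those changed by differentiation of keratinocytes with control siRNA, comparisons that share no library. In CAL27, 6058 regions were lower in both against 2673 for independent lists, and 4063 higher in both against 2178, while 2242 went opposite ways against 4833. In SCC13, 3181 were lower in both against 1071, and 1168 higher in both against 409, while 394 went opposite ways against 1451. The lowest of these 4 ratios, 1.87, goes with the hypothesis that p63 siRNA moves these lines partly the way differentiation moves keratinocytes. The correlation across regions was low, 0.19 in CAL27 and 0.22 in SCC13. Against differentiation with p63 siRNA the relation was weaker, with ratios of 1.8 for losses and 1.39 for gains in CAL27, and 2.29 and 2.22 in SCC13. Correlations there were 0.06 in CAL27 and 0.07 in SCC13. Independent lists do not match regions on level, so part of each ratio may come from level.

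Called regions may lie together on chromosomes. The fullest 1 Mb window held more calls than 95% of random placements in 6 of 10 comparisons and directions: all 5 directions of loss and the gains of differentiation, so the hypothesis failed for the 4 sets of gains with p63 siRNA. For p63 siRNA losses the smallest p that 1000 placements can give, 0.001, was reached in each of the 4 contexts (Benjamini-Hochberg adjusted 0.002). The window at 209 to 210 Mb of chromosome 1 was fullest in CAL27 (55 of 150 tested regions lower, 9 higher), SCC13 (24 lower, 1 higher, equal to 148 to 149 Mb of chromosome 5) and undifferentiated keratinocytes (66 lower, 16 higher), and also for losses in differentiation (52 lower, 12 higher). In differentiated keratinocytes with p63 siRNA the fullest window was 43 to 44 Mb of chromosome 19, with 58 lower and 10 higher regions of 111. The window at 152 to 153 Mb of chromosome 1 held 36 regions of 132 that opened in differentiation and 3 that closed. Neighbouring regions are not independent, so random placement is a lenient standard.

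Losses common to all 4 contexts were densest at 113 to 114 Mb of chromosome 2, with 14 of 136 tested regions and 0 gains there (permutation p = 0.02, adjusted 0.03 over 12 tests).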
